A study of Mus musculus with 15 samples.

How the data were processed

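The series comprised 15 samples of mouse cells, of which 6 were ChIP-seq and 9 were RNA-seq libraries. Peak lists of 5 ChIP-seq libraries were used: Mel18 in embryonic stem cells (ESCs) of the E14Tg2A line, and Mel18, Cbx2, Ring1b and RYBP in early cardiac mesoderm precursors (MES) derived from that line. The IgG ChIP-seq library of MES and the RNA-seq libraries were not analysed here. Per the labels' protocols, ESCs were grown in a medium with kinase inhibitors and LIF, MES were made with BMP4 at a dose that was typically 0.1 to 0.3 ng/ml, and chromatin was immunoprecipitated with 5 ug of antibody. The same Mel18 antibody lot was used in ESCs and MES per the labels.

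Each deposited list gave the chromosome, start and end of each peak, with a name that carried the tag of the MACS peak caller and 1 score per peak. Reads were placed on the mm9 build, and Bowtie and TopHat were the tools named, per the submitters' processing notes, which gave no versions. The caller's version, its settings, the control library and whether replicates were pooled were not given in the sources used here. The score was the authors' own value, and its scale was not stated in the deposited files. In the deposited lists the score started at 50, and values piled up at 3100 in 4 of the 5 lists. Because of this ceiling and the unknown scale, the authors' score was used only to rank or split peaks within 1 list and was never compared between lists. Peak starts in the deposited coordinates counted from 0 and are given here counted from 1, as a genome browser shows them.

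Read depth was unknown for all 5 libraries, so the number, width and score of peaks could not be corrected for it. Each list belonged to 1 sample, so differences between cell states or antibodies had no replicate check. Shares of peaks are given with exact Clopper-Pearson 95% intervals, which cover counting only. The Fisher and permutation tests compared these peak lists. Intervals and tests treat peaks as independent, but 1 stretch can be split into several peaks. The intervals can therefore be too narrow and the p-values too small. Peaks are not replicates, and the p-values do not measure the spread between cultures.

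A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. Chance overlap came from 1000 shuffles of each list within its chromosomes, with peak widths kept. Shuffled peaks could fall anywhere between the first and last peak of a chromosome. The chance values therefore make no allowance for kinds of sequence in which peaks tend to lie. Mel18 peaks were classed as ESC-only, MES-only or common from the overlap of both Mel18 lists. The share of each class that overlapped a MES Ring1b, Cbx2 or RYBP peak was compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 6 tests and a threshold of 0.05. Odds ratio intervals at 95% used the normal approximation on the log scale. Medians of score and width of shared and unshared peaks were compared within each list by a two-sided permutation test with 100000 resamples, adjusted over 10 tests. Each list was divided into 4 score quartiles of near-equal size. Domains were made by joining peaks of 1 list that lay within 10 kb of each other, and domains of 5 or more peaks were counted. Merged regions were made by joining overlapping peaks of all 5 lists, and the covered lengths of lists were compared in them, with a bootstrap of 2000 resamples for the interval of the median.

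Peak sets were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9. The overlap code was checked against bedtools 2.31.1 on all 20 ordered pairs of lists, with 0 peaks that differed under the 1 bp rule and 0 under the rule of 50% of the shorter peak. It was also tested on simulated data in which 59.9% of 6593 ESC Mel18 peaks were placed on MES Mel18 peaks. The placed peaks were centred on MES Mel18 peaks, so the recovery of 100% of them was set by construction and checked the code only. Of the randomly placed peaks, 0.909% were called as overlapping. The permutation test was simulated with smaller groups and fewer resamples than were used for the peaks. In 100 simulations it gave a p below 0.05 in 7 with no difference and in 100 with a shifted median.

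The tests, the overlap rule, the naming rule and the alternatives were fixed before the data were examined, except those named as added later. The alternatives were an overlap of at least 50% of the shorter peak, peak centres within 1 kb, the upper 50% of each list by score, lists of equal length, joining of peaks within 1 kb, autosomes without the sex chromosomes, joining gaps of 5 kb and 20 kb for domains, and circular shifts for chance. The comparisons by Ring1b peak, the split by score quartile, the merged regions and their covered lengths, stratification by score quartile, removal of 2 long domains, and the alternatives for covered length were added after the data were examined.

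No gene was assigned to any peak, because no annotation of mm9 was used here and coordinates were not moved between builds. The planned count of promoter targets and the planned counts over 13 fixed gene lists were therefore not run. In that case the naming rule took the 5 peaks with the highest score per class and the 5 domains with the most peaks per list, by coordinates. Score ties at 3100 were broken by width, a choice made after the ties were seen, and common peaks were ranked by the MES score. All coordinates are on mm9.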

Results

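Binding of 4 subunits of Polycomb repressive complex 1 (PRC1) was compared in mouse E14Tg2A embryonic stem cells (ESCs) and in early cardiac mesoderm precursors (MES) differentiated from them. Mel18, also called Pcgf2, is a PCGF subunit of PRC1, and Ring1b is the catalytic subunit that ubiquitinates histones. Cbx2 is a chromodomain subunit of canonical PRC1, and RYBP is a subunit of variant PRC1. Mel18 was mapped in both cell states, and Cbx2, Ring1b and RYBP were mapped in MES, with 1 ChIP-seq sample per list. Whether replicates were pooled in a list was not given. Read depth was unknown, and no gene was assigned to peaks, which are named by their mm9 coordinates.

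MES Mel18 and Cbx2 occupied fewer but broader sites than ESC Mel18, Ring1b and RYBP. The lists held 6593 peaks of ESC Mel18, 4165 of MES Mel18, 3679 of MES Cbx2, 8641 of MES Ring1b and 7614 of MES RYBP. Median peak width was 1103 bp for ESC Mel18 and 1855 bp for MES Mel18. It was 2508 bp for Cbx2, 1178 bp for Ring1b and 1476 bp for RYBP. Peaks of 10 kb or more numbered 47 in ESC Mel18 and 171 in MES Mel18, against 208 in Cbx2, 146 in Ring1b and 11 in RYBP. The widest MES Mel18 peak spanned 118119 bp on chromosome 6 (52101429 to 52219547), whereas the widest ESC Mel18 peak spanned 19802 bp. ESC Mel18 peaks covered 10.8 Mb and MES Mel18 peaks 11.95 Mb, so the shorter MES list covered more sequence. Cbx2, Ring1b and RYBP peaks covered 13.6, 15.3 and 13.0 Mb. With 1 sample per list no test between lists was possible, and peak number and width also depend on depth and calling.

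**Figure D1:**
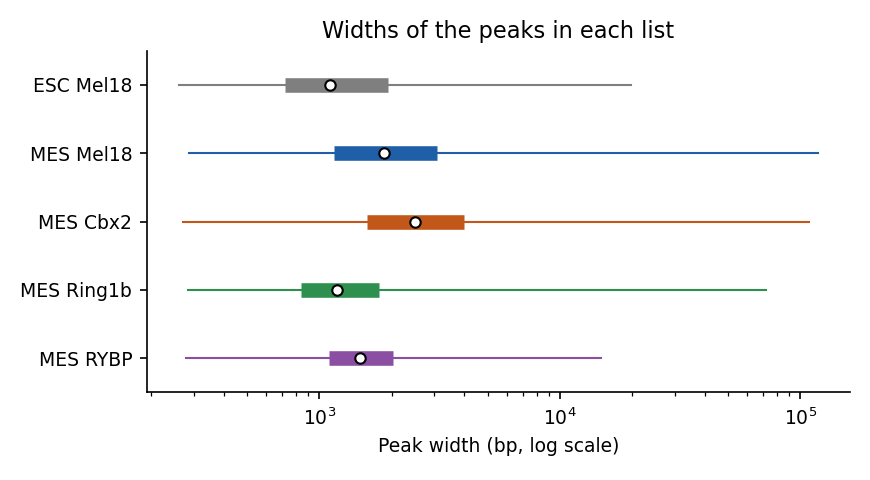
Peak width in bp on a log scale for the 5 lists, with thin lines from the narrowest to the widest peak, thick bars from the lower to the upper quartile and circles at the median. The MES Cbx2 and MES Mel18 medians, 2508 and 1855 bp, lie to the right of the other 3 lists.

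The Mel18 lists of ESCs and MES address which Mel18 sites were bound before and after commitment to mesoderm. Mel18 occupied a common set of high-scoring sites in both states, and sites found in 1 state were mostly low-scoring. Of the ESC Mel18 peaks, 3470 of 6593 (52.6%, interval 51.4 to 53.8) overlapped a MES Mel18 peak. Of the MES Mel18 peaks, 2760 of 4165 (66.3%, interval 64.8 to 67.7) overlapped an ESC Mel18 peak. This left 3123 ESC-only and 1405 MES-only peaks. Shuffled lists gave a mean overlap of 0.744% for ESC peaks (range 0.455 to 1.14%) and 1.09% for MES peaks (range 0.60 to 1.61%). Which share was higher depended on the peaks taken: with the 3679 highest-scoring peaks from each list, 73.2% of ESC peaks and 62.0% of MES peaks were shared. That setting changed list length and score make-up together.

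Sharing rose with score in both states. In ESCs, 17.5% of Mel18 peaks in the lowest score quartile were shared with MES, 37.2% in the second, 64.9% in the third and 91.0% (interval 89.5 to 92.4) in the highest. In MES, the shares on ESC peaks were 31.9, 58.9, 78.6 and 95.8% (interval of the last 94.4 to 96.9). The lower 2 quartiles held 76.7% of the ESC-only peaks and 81.0% of the MES-only peaks. Shared ESC Mel18 peaks had a median score of 363 against 73.7 for ESC-only peaks, and a median width of 1685 bp against 785 bp. Shared MES Mel18 peaks had a median score of 291 against 72.9 for MES-only peaks, and a median width of 2402 bp against 1079 bp. Cbx2, Ring1b and RYBP peaks that overlapped a MES Mel18 peak were wider and scored higher than those that did not. Median width was 3058 against 1355 bp for Cbx2, 1773 against 982 bp for Ring1b and 1799 against 1283 bp for RYBP. All 10 permutation tests of score and width gave 1e-05, the smallest p that the resamples can give, before and after adjustment.

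**Figure D2:**
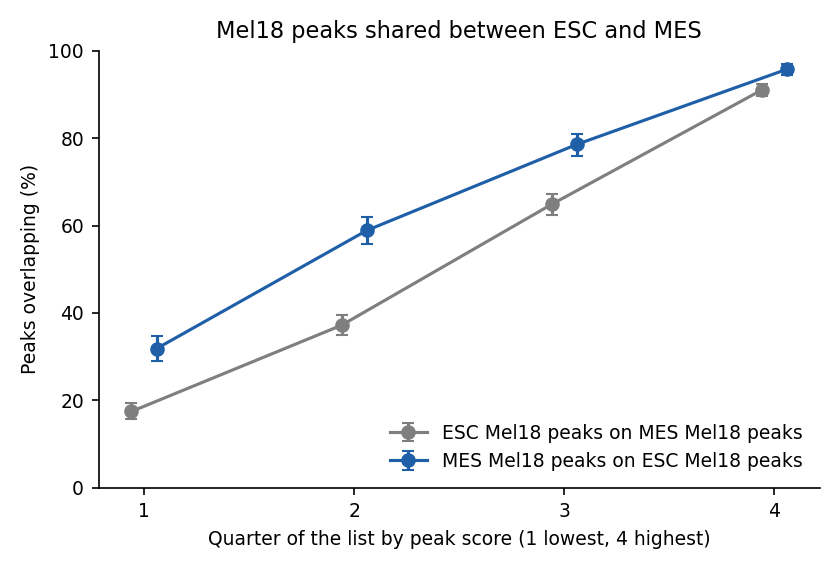
Percent of Mel18 peaks that overlapped a Mel18 peak of the other cell state, by quartile of the list in order of score, with exact 95% intervals as bars. In ESCs the share rose from 17.5 to 91.0%, and in MES from 31.9 to 95.8%.

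Sites bound by Mel18 in both states were covered by longer stretches in MES. In 2540 merged regions with Mel18 peaks in both states, MES peaks covered a median of 1.24 times the length of ESC peaks (bootstrap interval 1.22 to 1.27), and the MES length was the greater in 1903 regions (74.9%). In 1911 regions with peaks of all 5 lists, the median length relative to ESC Mel18 was 1.27 for MES Mel18, 1.45 for Cbx2, 1.12 for Ring1b and 0.877 for RYBP. These ratios set single lists of unknown depth against each other.

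The common Mel18 peaks with the highest MES scores lay on chromosome 8 (107790039 to 107796374), chromosome 11 (57640294 to 57652144), chromosome 1 (74994162 to 75000371), chromosome 19 (45148980 to 45156214) and chromosome 10 (114236997 to 114240465). All 5 overlapped Cbx2, Ring1b and RYBP peaks in MES. The MES-only peaks with the highest scores lay on chromosome 5 (148032393 to 148037028 and 120129690 to 120140283), chromosome 1 (138841079 to 138851646), chromosome 18 (36439904 to 36448068) and chromosome 4 (82147928 to 82155370). These 5 peaks also overlapped all of the other MES subunits. The ESC-only peaks with the highest scores lay in 2 long domains, on chromosome 15 (102779725 to 102786041, 102800926 to 102815866 and 102819844 to 102832472) and on chromosome 11 (96200882 to 96216808 and 96139829 to 96155379). None of these 5 overlapped a MES Ring1b peak, whereas all 5 overlapped RYBP peaks and the 2 on chromosome 11 overlapped a Cbx2 peak. Outside those domains, in a ranking of the autosomes and the X chromosome chosen after the values were seen, the ESC-only peaks with the highest scores lay on chromosome 13 (115245755 to 115251361), chromosome 11 (23977867 to 23983044), chromosome 3 (130811764 to 130816560 and 148650117 to 148654015) and chromosome 17 (8624676 to 8629149). Of these, 3 overlapped a MES Ring1b peak, and the peak on chromosome 3 from 130811764 overlapped no MES peak of any subunit.

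The MES lists address which PRC1 subunits lay at the Mel18 sites of mesoderm precursors. Under the 1 bp rule, Ring1b peaks overlapped 81.2% of MES Mel18 peaks (interval 79.9 to 82.3), Cbx2 peaks 73.3% (71.9 to 74.6) and RYBP peaks 72.4% (71.1 to 73.8). Shuffled lists gave means of 1.56, 0.973 and 1.39%. All 3 subunits were found at 2404 of 4165 peaks (57.7%, interval 56.2 to 59.2) and none at 436 (10.5%, interval 9.55 to 11.4). Ring1b with Cbx2 and without RYBP was found at 384 peaks (9.22%), and Ring1b with RYBP and without Cbx2 at 436 peaks (10.5%). The share with all 3 depended on the rule, at 44.1% with peak centres within 1 kb and 45.5% with 3679 peaks per list. The order of the subunits depended on the rule. With the 3679 highest-scoring peaks per list, Cbx2 peaks overlapped 79.5% of Mel18 peaks and Ring1b peaks 68.3%. With peak centres within 1 kb, RYBP was at 64.4% and Cbx2 at 60.3%. With peaks within 1 kb joined, RYBP was at 78.1% and Cbx2 at 71.3%.

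**Figure D3:**
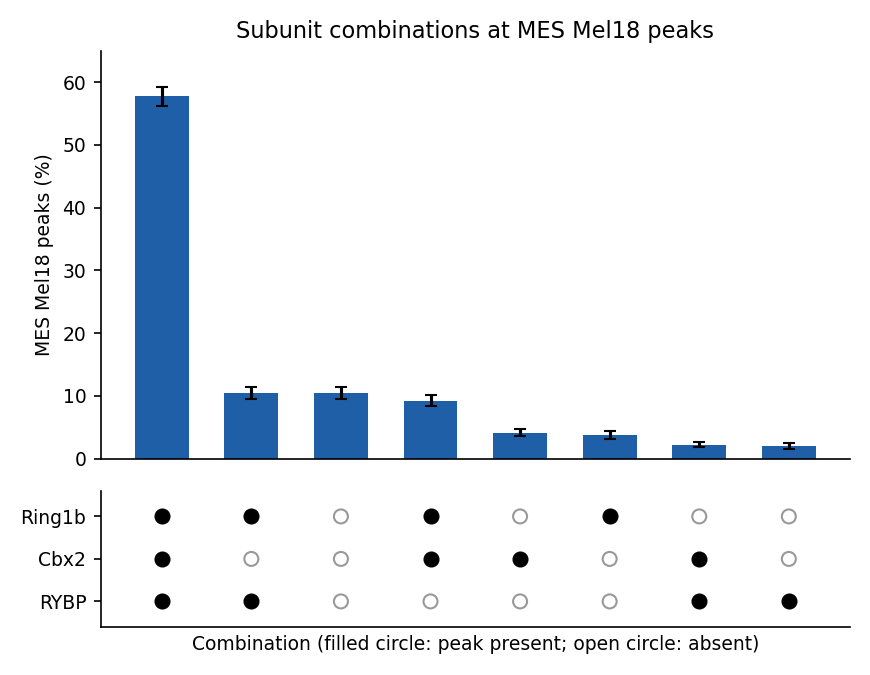
Percent of the 4165 MES Mel18 peaks that overlapped each combination of Ring1b, Cbx2 and RYBP peaks, with exact 95% intervals as bars and filled circles for the subunits present. Mel18 peaks with all 3 subunits made up 57.7%, and each other combination was at or below 10.5%.

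Cbx2 and RYBP, which belong to different forms of PRC1, were associated across Mel18 sites. Both were present at 2497 Mel18 peaks, Cbx2 without RYBP at 556, RYBP without Cbx2 at 520 and neither at 592. The odds ratio was 5.11 (interval 4.40 to 5.94, Fisher's exact test p = 4.49e-104). It was 2.93 in the upper 50% of each list by score and 8.45 with peaks within 1 kb joined. It was not stratified by score quartile, so how much of it went with peak score was not tested. In the lowest score quartile, Cbx2 was found at 33.4% and RYBP at 45.2% of Mel18 peaks. Mel18 peaks with all 3 subunits had a median score of 412 and a median width of 2674 bp, against 57.3 and 709 bp for those with none. In the highest score quartile, Cbx2 was found at 99.4%, Ring1b at 99.5% and RYBP at 96.8% of Mel18 peaks. In that quartile Cbx2 peaks covered 97.5% and Ring1b peaks 89.9% of the bases of Mel18 peaks, whereas RYBP peaks covered 58.1%.

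The Mel18 peaks with Cbx2 and without RYBP that scored highest lay on chromosome 9 (89776077 to 89778661 and 91303586 to 91306203), chromosome 17 (26983317 to 26985866), chromosome X (133638527 to 133641448) and chromosome 14 (104857002 to 104859599), and all 5 overlapped Ring1b. Those with RYBP and without Cbx2 lay on chromosome 13 (44826086 to 44826918), chromosome 2 (118374107 to 118376037) and chromosome 19 (37769646 to 37774920, 47036537 to 47037460 and 37766445 to 37769375), and 3 of these overlapped Ring1b. Those with neither lay on chromosome 7 (19716284 to 19717258), chromosome 3 (94281555 to 94282373), chromosome 6 (88851663 to 88853322), chromosome 5 (124561536 to 124562693) and chromosome 4 (138935853 to 138936810), and 1 of them, on chromosome 6, overlapped Ring1b. With Cbx2 and RYBP both present, the highest scores were those of the common peaks on chromosomes 8, 11, 1 and 19 and of the MES-only peak on chromosome 5 from 148032393.

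Sites that kept Mel18 differed in MES subunits from sites where Mel18 was found in 1 state. By definition, ESC peaks shared with MES overlap a MES Mel18 peak and ESC-only peaks do not. Their contrast therefore measures how MES subunits go with MES Mel18 across ESC peaks, and is not a separate trait of kept sites. Among ESC-only Mel18 peaks, 32.3% (interval 30.7 to 34.0) overlapped MES Ring1b, 10.7% (9.66 to 11.9) Cbx2 and 36.3% (34.6 to 38.0) RYBP. Among ESC Mel18 peaks shared with MES, the shares were 94.3, 86.8 and 84.4%. The odds ratios were 0.0291 (interval 0.0247 to 0.0342) for Ring1b, 0.0183 (0.0158 to 0.0213) for Cbx2 and 0.106 (0.0939 to 0.119) for RYBP, with p-values too small for the software to write. Under the other overlap and list rules they ranged from 0.0217 to 0.0565 for Ring1b, 0.0119 to 0.0426 for Cbx2 and 0.0708 to 0.239 for RYBP. Of the ESC-only peaks, 1434 (45.9%) overlapped at least 1 of these subunits in MES, and 1689 (54.1%) overlapped none.

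Among MES-only Mel18 peaks, Ring1b was found at 54.7% (interval 52.1 to 57.4), Cbx2 at 52.1% (49.4 to 54.7) and RYBP at 42.5% (39.9 to 45.1). Among MES Mel18 peaks shared with ESCs, the shares were 94.6, 84.1 and 87.7%. The odds ratio was 0.0690 for Ring1b (adjusted p = 2.57e-205), 0.206 for Cbx2 (adjusted p = 5.12e-104) and 0.104 for RYBP (adjusted p = 2.02e-203), from Fisher's exact test with Benjamini-Hochberg adjustment. Under the other overlap and list rules they ranged from 0.0618 to 0.123 for Ring1b, 0.151 to 0.378 for Cbx2 and 0.101 to 0.215 for RYBP. All 3 subunits were found at 25.2% of MES-only peaks and at 74.3% of those shared. Part of these gaps went with peak score, most of all the gap for Cbx2 at MES-only peaks. Stratified by score quartile, an alternative chosen after the data were examined, the odds ratios of ESC-only peaks were 0.0603 for Ring1b, 0.0294 for Cbx2 and 0.247 for RYBP. Those of MES-only peaks were 0.168 for Ring1b, 0.693 for Cbx2 (Mantel-Haenszel interval 0.580 to 0.829) and 0.196 for RYBP.

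**Figure D4:**
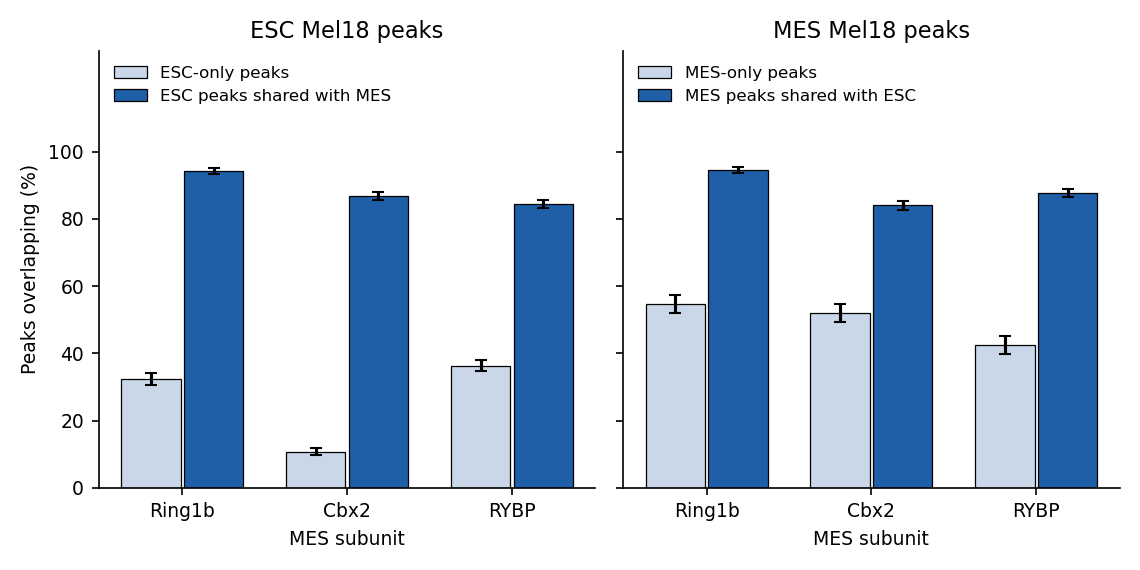
Percent of Mel18 peaks that overlapped MES Ring1b, Cbx2 and RYBP peaks, for ESC peaks on the left and MES peaks on the right, with peaks of a single state in light bars, common peaks in dark bars and exact 95% intervals. ESC-only peaks, which lack a MES Mel18 peak by definition, overlapped Cbx2 in 10.7% and MES-only peaks in 52.1% of cases.

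Mel18 peaks lay in long domains on chromosomes 2, 6, 11 and 15 in ESCs, and MES Mel18 peaks covered those on chromosomes 2 and 6. ESC Mel18 formed 78 domains of 5 or more peaks and MES Mel18 39, against 23 for Cbx2, 62 for Ring1b and 67 for RYBP. These counts depend on how a stretch was split into peaks, since the chromosome 6 domain held 26 ESC Mel18 peaks and 4 wider MES Mel18 peaks. In the upper 50% of each list by score, the counts fell to 30 for ESC Mel18 and 10 for MES Mel18. The ESC Mel18 domain with the most peaks lay on chromosome 6 (52099937 to 52225638, 26 peaks). There MES Mel18, Cbx2 and Ring1b peaks covered 98.7, 99.5 and 98.6% of the length and RYBP peaks 66.5%. The domain on chromosome 2 (74492633 to 74602362, 24 peaks) was covered by MES Mel18 at 92.0%, Cbx2 at 94.3% and Ring1b at 90.6%.

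The domains on chromosomes 15 and 11 had few or no MES Mel18 and Ring1b peaks, and read coverage there was not analysed here. On chromosome 15 (102739698 to 102872665), 24 ESC Mel18 peaks and 25 MES RYBP peaks were present, and MES Mel18, Cbx2 and Ring1b had 0 peaks. Outside that domain, MES Mel18 peaks lay before it (102735291 to 102736423 and 102737222 to 102737941). Cbx2 peaks lay on both sides (102735287 to 102736135 and from 102874832), and a Ring1b peak lay after it (102881385 to 102882018). On chromosome 11 (96112916 to 96236534), MES Mel18 covered 10.6% and Ring1b 3.32% of the length, whereas Cbx2 covered 91.8% and RYBP 64.2%. The other of the 5 ESC Mel18 domains with the most peaks, on chromosome 18 (37874217 to 37928073), held 19 ESC Mel18 peaks, 14 MES Mel18, 12 Cbx2, 18 Ring1b and 12 RYBP peaks. MES Mel18 domains with the most peaks lay on chromosome 18 (37866628 to 37928876), chromosome 9 (91244624 to 91315959), chromosome 12 (50473329 to 50504705), chromosome 1 (19195672 to 19233438) and chromosome X (133632729 to 133662742). These 5 domains were bounded and ranked by MES Mel18 peaks, which favours MES cover. On chromosome 18, MES Mel18 covered 47.3% and ESC Mel18 42.8% of the domain, on chromosome 9 84.8 and 43.0%, on chromosome 12 94.3 and 70.8%, on chromosome 1 84.0 and 38.2%, and on chromosome X 46.3 and 16.7%.

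Cbx2 had its most peaks in the chromosome 9 domain (13 peaks) and in those on chromosome 18 (13), chromosome 1 (9), chromosome 2 (8) and chromosome 13 (78301173 to 78352135, 7). On chromosome 13, in a domain bounded by Cbx2 peaks, Cbx2 covered 91.5% and MES Mel18 94.6% of the domain, against 31.9% for ESC Mel18 and 25.9% for RYBP. Ring1b had its most peaks on chromosome 18 (18), at the start of chromosome 9 (2999897 to 3036919, 12), on chromosome X (11705650 to 11737405, 11), on chromosome 13 (40796649 to 40840282, 9) and on chromosome 14 (122863584 to 122890867, 9). The domain at the start of chromosome 9 held 16 ESC Mel18 peaks and 0 MES Mel18 and Cbx2 peaks, and whether its peaks reflect binding was not tested. RYBP had its most peaks in the domains on chromosomes 11 (28), 15 (25), 2 (23), 6 (21) and 18 (12).

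**Figure D5:**
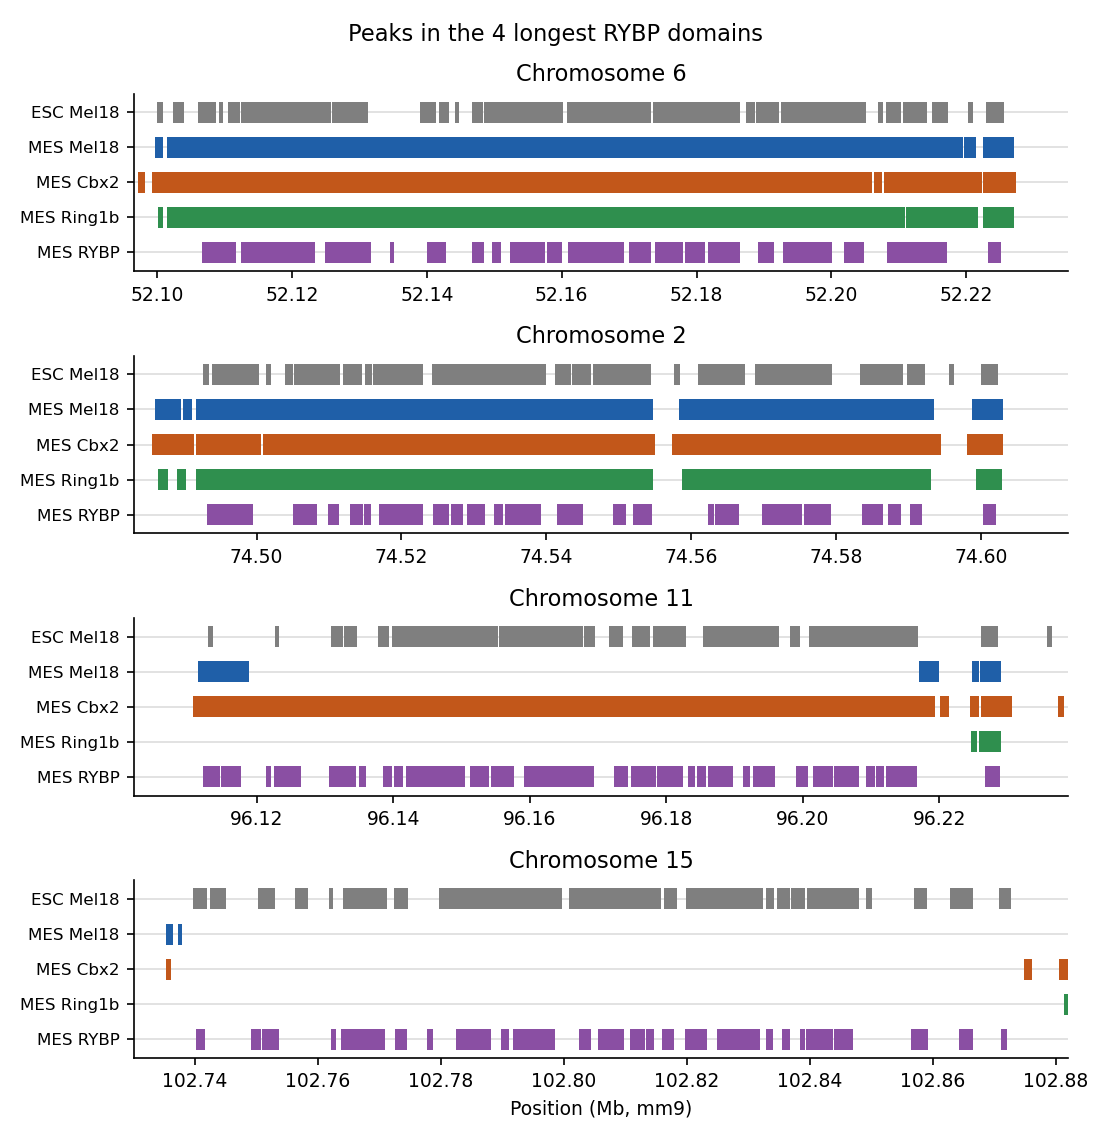
Map of the 4 RYBP domains of 100 kb or more, on chromosomes 6, 2, 11 and 15, with position in Mb on mm9 and 1 line of peaks per list. MES Mel18 and Ring1b peaks cover most of the domains on chromosomes 6 and 2. On chromosome 11 they cover 11.8 and 3.40% of the domain, whereas Cbx2 peaks cover 96.4%. On chromosome 15, MES Mel18, Ring1b and Cbx2 peaks cover 0% of the domain, and some of their peaks lie outside it in the plotted window. ESC Mel18 and RYBP peaks are present in all 4 domains.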

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

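No paired analysis was possible because each group had 1 sample. All 55 odds ratios and all 20 differences of median score or width recomputed under the alternatives kept their direction and their side of 0.05. Their size was less stable, since the odds ratio of Cbx2 with RYBP was 2.93 in the upper 50% of each list by score and 8.45 with peaks within 1 kb joined. Stratification by score quartile, removal of the 2 long domains on chromosomes 11 and 15, the alternatives for covered length and those for Ring1b peaks with RYBP and without Mel18 were added after the data were examined. Removal of the 2 domains and restriction to autosomes each left all 15 recomputed results within their intervals or on the same side of the threshold, and circular shifts gave a chance overlap of 0.745%. The shares of overlapping peaks moved under other rules. By construction, requiring 50% of the shorter peak can only lower a share that rests on overlap alone. The share of Ring1b peaks with RYBP and without Mel18 could move either way. Lists of equal length changed list length and score make-up together, and the causes of the moves were not tested further. With 50% of the shorter peak required, Ring1b was found at 79.0%, RYBP at 69.3% and all 3 subunits at 55.4% of MES Mel18 peaks. With centres within 1 kb, 40.6% of ESC and 61.1% of MES Mel18 peaks were shared, Ring1b, Cbx2, RYBP and all 3 were at 75.8, 60.3, 64.4 and 44.1% of MES Mel18 peaks, and 31.7% of Ring1b peaks had RYBP without Mel18. In the upper 50% of each list by score these values were 60.6, 77.3, 93.0, 83.6, 72.9, 63.4 and 27.0%, and MES Mel18 covered 1.27 times the ESC Mel18 length. By construction that setting cut the lists to 3297 (ESC Mel18), 2083 (MES Mel18), 1840 (Cbx2), 4321 (Ring1b) and 3807 (RYBP) peaks and left 30 ESC and 10 MES Mel18 domains. With 3679 peaks per list the 7 shares, in that order, were 73.2, 62.0, 68.3, 79.5, 56.5, 45.5 and 16.0%. With peaks within 1 kb joined they were 49.8, 70.9, 83.7, 71.3, 78.1, 62.0 and 31.5%. Promoter distances of 1 kb and 5 kb, and the other settings for promoter targets and gene lists, were not run because no gene was assigned. Read depth was unknown, so a site without a peak is not shown to be unbound.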

Other observations

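The comparisons by Ring1b peak were chosen after the data were examined. Ring1b peaks in MES with and without Mel18 differed in the other subunits whose peaks they overlapped. Of 8641 Ring1b peaks, 2994 (34.6%) overlapped Mel18 and RYBP, 668 (7.73%) Mel18 without RYBP, 2596 (30.04%) RYBP without Mel18 and 2383 (27.6%) neither. Cbx2 was found at 83.3% (interval 82.0 to 84.5) of Ring1b peaks with Mel18 and at 9.24% (8.45 to 10.1) of those without, an odds ratio of 48.9 (42.9 to 55.6). RYBP was found at 81.8% of Ring1b peaks with Mel18 and at 52.1% of those without, an odds ratio of 4.11 (3.72 to 4.55, Fisher's exact test p = 1.64e-186). These odds ratios were not stratified by score, so how much of them went with peak score was not tested. Ring1b peaks without Mel18 had a median score of 80.4 against 248 for those with Mel18. Their median width was 982 against 1772.5 bp. Ring1b peaks with RYBP and without Mel18 or Cbx2 numbered 2227 and had a median score of 97.3 and a median width of 1114 bp, against 388 and 2198 bp for the 2546 with all of Mel18, Cbx2 and RYBP. With lists of equal length, Ring1b peaks with RYBP and without Mel18 made up 16.0%.

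Among RYBP peaks, 1476 of 7614 (19.4%, interval 18.5 to 20.3) overlapped no Mel18, Cbx2 or Ring1b peak in MES, and their median score was 68.6. Of Cbx2 peaks, 459 of 3679 (12.5%, interval 11.4 to 13.6) overlapped no other MES list. At the start of the assembled chromosome 9 (2999887 to 3038554), ESC Mel18 had 17 peaks, Ring1b 12 and RYBP 2, with highest scores of 632, 197 and 51.9 in their own lists, whereas MES Mel18 and Cbx2 had 0. On the mitochondrial genome, ESC Mel18 had 1 peak with a score of 3100 and Ring1b 1 peak with a score of 254. The ESC Mel18 peaks at both places counted as ESC-only. Whether the peaks at these places reflect binding was not tested.

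Of the patterns below, the tests on loss of subunits in the 2 long domains and the test of the calling threshold were chosen after the results were seen. Of the 4 ESC Mel18 domains of 100 kb or more, 2 had few or no MES Ring1b and Mel18 peaks: on chromosome 15 (102739698 to 102872665) both covered 0%, and on chromosome 11 (96112916 to 96236534) Ring1b covered 3.32% and Mel18 10.6%. The tables argue against loss of every PRC1 subunit in MES, since RYBP covered at least 52.6% of each, and against joint loss of Mel18, Ring1b and Cbx2 on chromosome 11, where Cbx2 covered 91.8%. That very long regions were lost by the peak caller stays open. Of the 62 RYBP domains of 5 or more peaks and under 50 kb, 0 had Mel18, Ring1b and Cbx2 each covering under 5%. However, the domains of similar length on chromosomes 6 and 2 were covered at 90.6 to 99.5% by these lists. On chromosome 11, MES Mel18 peaks lay at 96111446 to 96118835 and from 96216975, near both ends of a Cbx2 peak (96110689 to 96219299). That Cbx2 peak scored 1215, and on chromosome 6 the widest Cbx2 and Mel18 peaks scored 1399 and 1923. On chromosome 2 the widest scored 3100 and 3131. The widest Ring1b peak scored 3100 on chromosome 6 and 2582 on chromosome 2. Among peaks of 10 to 30 kb, 165 of 196 Cbx2, 150 of 162 MES Mel18 and 128 of 140 Ring1b peaks scored 3100 or more. On chromosome 15, MES Mel18 and Cbx2 peaks lay before the domain, from 102735291 and 102735287. A Cbx2 peak from 102874832 and a Ring1b peak from 102881385 lay after it. The edge peaks and the lower Cbx2 and Mel18 scores go with lost calls, whereas the Ring1b score on chromosome 6 does not. These values do not decide. Loss of Mel18, Ring1b and Cbx2 on chromosome 15, where these lists covered 0%, cannot be told apart from lost calls, because no read coverage was analysed here, and a difference between ESCs and MES stays open as untested.

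ESC-only Mel18 peaks were mostly low-scoring, which a calling threshold could produce. In the upper score quartile outside the 2 long domains, 128 of 1628 ESC peaks (7.86%, interval 6.60 to 9.28) were ESC-only. That share lies above the 5% set in the test for a threshold as the whole cause. It does not decide on a threshold, because enrichment in the MES Mel18 library is unknown. Loss of all PRC1 subunits at most of these 128 sites is argued against, since 86.7% (interval 79.6 to 92.1) overlapped a MES Ring1b, Cbx2 or RYBP peak. It is not argued against at the 17 sites (13.3%) that overlapped none. The 128 include the mitochondrial peak and the highest-scoring peak at the start of chromosome 9, where binding was not tested. Ring1b was found at 71.1%, RYBP at 71.1% and Cbx2 at 14.8% of the 128 sites in MES. These 3 subunits were not mapped in ESCs in the lists used here. A threshold, a lower enrichment in the MES library and a difference between the cell states stay open.

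RYBP peaks covered 58.1% (bootstrap interval 56.7 to 59.4) of the bases of MES Mel18 peaks in the highest score quartile, against 97.5% for Cbx2 and 89.9% for Ring1b. Narrow RYBP calls at every site are argued against by 2397 merged regions with Ring1b and RYBP and without MES Mel18. There the median log2 ratio of RYBP to Ring1b length was 0.21 (interval 0.19 to 0.23). It was -0.23 in 2648 regions with MES Mel18. The regions without MES Mel18 were shorter, with a median Ring1b length of 1159 against 2262.5 bp, so they do not test narrow RYBP calls at broad sites. Peaks of 10 kb or more numbered 11 in RYBP and 146 in Ring1b, and narrow calls at broad sites stay open. Short gaps between RYBP calls are argued against as well, since RYBP peaks joined within 3 kb covered 64.8% (interval 63.2 to 66.3), under the 90% set for the test. The antibody, the depth and the sensitivity of the RYBP library, and a difference between the subunits, were not tested and stay open.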
